A study of Homo sapiens with 30 samples.

How the data were processed

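RUES2 cells, a human embryonic stem cell line, were grown in E7 medium. They were given Wnt3a at 100 ng/mL with or without CPI-203 at 1 µM, an inhibitor of the BET bromodomain proteins that bind acetylated chromatin, on day 1, and then Activin A at 10 ng/mL or none on day 2, per the labels. RNA sequencing covered 16 libraries in 8 groups of 2, and ATAC sequencing, which marks open chromatin, covered 14 libraries in 7 groups of 2. At 24 h the RNA groups were E7 (untreated), E7_CPI, WNT and WNT_CPI. At 48 h they were E7_ACT, WNT_E7 (Wnt3a, then medium alone), WNT_ACT and WNT_CPI_ACT (Wnt3a with CPI-203, then Activin A). Nothing in the labels says whether replicates came from separate cultures, so the p-values measure only the spread between these samples.

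The deposited RNA values were raw counts per gene, 1 table per replicate number, with Entrez gene IDs and symbols. The submitters' processing notes list featureCounts, DESeq2, Bowtie2, MACS2 and deepTools. The aligner and genome build used for the RNA counts were not given in the sources used here. Of the 27360 genes with values for replicate 1, 27348 also had values for replicate 2, which had no others. For 27322 of these IDs a symbol was taken from the RefSeq table of the human assembly, and 239 symbols differed between the tables. The other deposited file, of peak positions in another unit than counts (base pairs, per the file headers), held 1 combined list of ATAC peaks without signal, score or sample columns, so no ATAC comparison could be tested. Its build was assumed to be GRCh37 and was not tested against chromosome lengths.

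In the replicate 1 table, the E7_CPI column did not follow the gene order of its own table. Its highest absolute Spearman correlation with any other library was 0.0071 as deposited. Read in the gene order of the replicate 2 table, its correlations were 0.954 to 0.986, against at most 0.0142 in 100 random orders, and 12 cells at its foot were empty. This column was left out of the tests, which leaves E7_CPI with 1 library (replicate 2) that is assumed to vary like the other groups. It was used only in alternatives chosen after the data were seen, and there in the replicate 2 gene order.

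In the 15 fitted libraries, 15478 to 16327 genes had at least 10 counts, and the 20 most counted genes took 5.74% to 8.87%. Of the 626 genes that the RefSeq table places on chromosome 22, 625 had no count in any fitted library, against 8.6% to 23.1% of the genes on each other autosome and X. Changes of genes on chromosome 22 could therefore not be seen, 9 list members among them.

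Counts were fitted with edgeR 4.0.16 in R 4.3.3, with limma 3.58.1: filterByExpr by group, TMM scaling (factors 0.945 to 1.047), and the quasi-likelihood F-test (2-sided) in a single model of the 8 groups with 7 residual degrees of freedom. Of all genes, 17793 were tested. P-values were adjusted by Benjamini-Hochberg over all genes of a comparison, and a gene was called at an adjusted p under 0.05. Values are log2 fold changes with their standard error (SE), over 2 libraries per group unless stated. Levels are CPM, counts scaled to a common library size as edgeR does from the TMM-scaled totals, as mean ± SD over 2 libraries.

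The replicate numbers paired the samples: across 13589 genes, deviations from the group mean correlated between replicates of different groups at r = 0.492 to 0.917 in all 21 pairs of groups without E7_CPI. The fit had no replicate term. A fit with the replicate number as a block was run beside it, and its value is given with the counts of calls and with the genes and lists named in the text where it changed the call or moved the count by over 1.5 times. The common biological coefficient of variation was 0.29 without and 0.122 with the block.

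Each of 24 gene lists was tested in 11 comparisons with limma's camera on log2 CPM (prior count 2), with a preset correlation of 0.01 between genes and, as an alternative, an estimated correlation. The lists were pluripotency, primitive streak and early mesoderm, definitive endoderm and anterior streak, canonical Wnt targets, Activin and Nodal targets, BMP targets, FGF and MAPK targets, immediate early genes, neuroectoderm, trophoblast and amnion, fibroblast, epithelial, mesenchymal transition, genes raised and genes lowered by BET inhibition elsewhere, BET and P-TEFb genes, ribosome biogenesis, cholesterol synthesis, S phase, G2 and M phase, p53 targets, unfolded protein and amino acid stress, hypoxia and glycolysis, and HOX genes. Adjustment was over all 264 tests: 85 passed with the preset correlation, and 16, all among the 85, with an estimated one. The drop does not rest on higher correlation alone. In WNT_CPI vs WNT, genes raised by BET inhibition elsewhere had an estimated correlation of -0.048, below the preset one. Their adjusted camera p still went from 1.02e-09 to 0.0133. With the replicate block, 81 passed with the preset correlation (69 shared with the 85) and 1 with an estimated one, canonical Wnt targets in WNT_CPI vs E7_CPI. The other 15 calls with an estimated correlation held only without the block. Lists not named in a comparison appear in the figure of the lists alone. fry was run too. Its directional p asks whether the genes of a list move, on balance, one way, and its mixed p whether they change in either direction; neither compares the list with other genes. Directional fry passed 50 tests (41 shared with camera) and mixed fry 116 (54 shared).

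Named genes followed a fixed rule. It took the called genes with an official symbol, a mean log2 CPM of at least 2 and the same direction in both replicates. In comparisons with E7_CPI the direction was checked in replicate 2 alone. The rule then took the 6 largest rises and the 6 largest falls in the main comparisons. For the interaction it took 4 and 4, and for the other comparisons of 2 groups 3 and 3. It added a panel of 22 genes, and up to 4 called members with the smallest adjusted p from each list that passed camera or had at least 3 called members. The groups, comparisons, tests, lists, named-gene rule and the alternatives that follow were set before the data were examined. These were DESeq2 1.42.0 size factors, the DESeq2 Wald test, library totals without TMM, a looser and a stricter count filter, a fit on the compared groups alone, a fold threshold, the block, and leaving out each library in turn. The difference of the CPI-203 effect between 48 h and 24 h the use of the reordered column and camera with both the block and an estimated correlation were added after the data were seen. A level in a group with no counts was bounded at 3 counts over the group.

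The procedure was tested on simulated data with a batch effect between replicates, with 50 changed genes at each of 4 fold sizes in WNT vs E7 and in E7_CPI vs E7. In WNT vs E7 it called 0 of 50 genes at 1.5-fold, 9 at 2-fold, 33 at 4-fold and 43 at 8-fold, and in E7_CPI vs E7, with 1 library, 0, 5, 26 and 44. With the block it called 24, 38, 47 and 50 genes in WNT vs E7, and 5, 32, 44 and 50 in E7_CPI vs E7. False calls were 0 without and 5 with the block. Camera passed the changed list of 25 genes in both, and 1 and 2 of 100 unchanged lists at an unadjusted p under 0.05. Apart from the batch effect the simulated genes varied independently, and the unchanged lists were random genes. These rates therefore do not cover lists of correlated genes, such as definitive endoderm genes (estimated correlation 0.382). Figures were drawn with matplotlib 3.10.9 in Python 3.11.15, with pandas 2.3.3 and numpy 2.4.6. Results for some items are left out of the text.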

Results

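The data covered the response of RUES2 human embryonic stem cells to Wnt3a, to the BET inhibitor CPI-203 and to Activin A, as gene counts from 16 RNA libraries (8 groups of 2) and as a combined list of open chromatin positions from 14 ATAC libraries (7 groups of 2). Totals of the 15 fitted libraries ran from 36268324 counts in WNT replicate 2 to 43347733 in WNT_CPI replicate 2. E7_CPI was represented by 1 library, and every other group by 2. In a principal component analysis of the fitted libraries, the first component held 45.1% of the variance, the second 21.7% and the third 13.4%. On the second component all replicate 1 libraries had positive and all replicate 2 libraries negative values (in E7, 12.9 and -35.1).

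**Figure D1:**
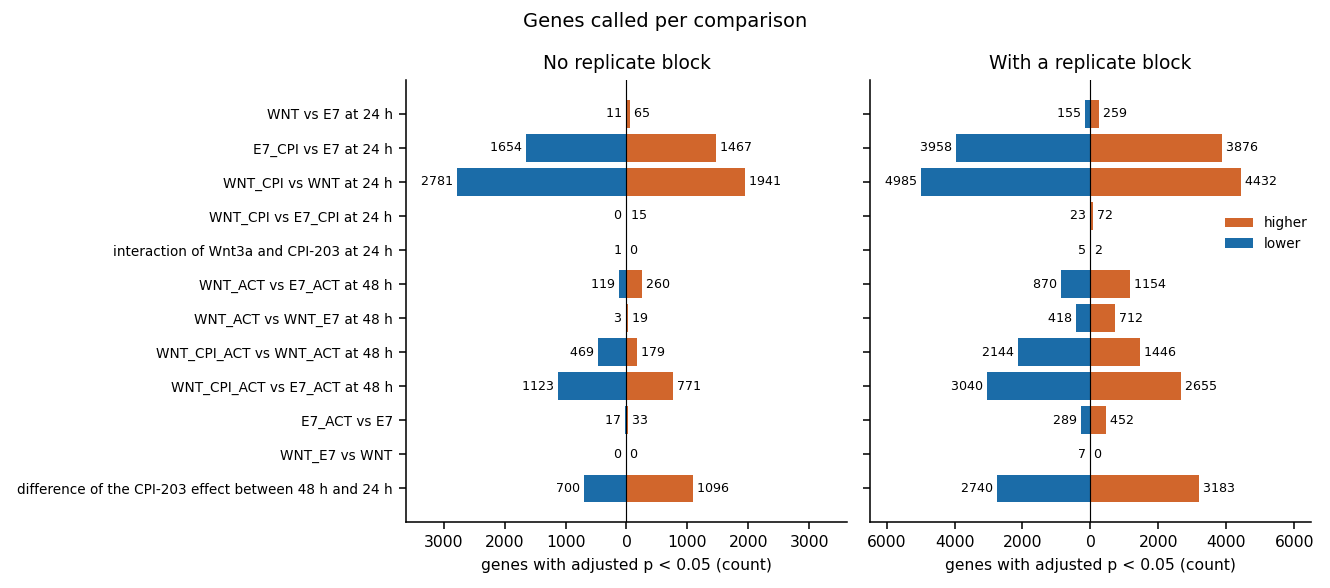
Genes called (adjusted p under 0.05) as higher (right) or lower (left) in each comparison, as counts of genes, without (left panel) and with (right panel) the replicate number as a block. The comparisons with CPI-203 at 24 h hold the most calls, 3121 and 4722 without the block.

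The first question was what 1 day of Wnt3a changed. Wnt3a raised direct targets of the Wnt pathway: SP5, a transcription factor switched on by beta-catenin, stood at 0.0718 CPM in E7 (3 counts in each library) and at 84.9 ± 9.0 CPM in WNT (adjusted p = 0.00109). The Wnt ligand WNT5B rose by 5.03 (SE 0.52, adjusted p = 0.00392) on the log2 scale, the Activin antagonist FST by 4.32 (SE 0.42), FOXB1 by 4.11 (SE 0.63) and GBX2 by 3.59 (SE 0.61). The feedback inhibitor APCDD1 rose by 3.53 (SE 0.52) and LEF1, a DNA-binding partner of beta-catenin, by 3.48 (SE 0.58). SHISA2, an inhibitor of Wnt and FGF receptors, fell by 4.03 (SE 0.67), the secreted Wnt antagonist SFRP1 changed by -2.996 (SE 0.39, adjusted p = 0.0137), SEZ6 fell by 2.72 (SE 0.45), TESC fell by 1.84, SYP fell by 1.83 and TMEM151B fell by 1.41.

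Of the 14 canonical Wnt targets measured, 6 rose and 0 fell (9 and 0 adjusted over the list alone). NKD1 (2.04, SE 0.18) and RNF43 (2.08, SE 0.31) were among them. AXIN2, a feedback target, differed by 1.05 (SE 0.22, adjusted p = 0.123) and was called with the block (adjusted p = 0.0157). The list lay higher than other genes (median 1.86, 1.55 with its member at 0 counts bounded, adjusted p = 1.37e-19, and 0.00716 with an estimated correlation). Of 19 primitive streak and early mesoderm genes, which mark the cells that leave the epiblast, 1 rose and 0 fell (7 and 0 adjusted over the list alone). The list lay higher (median 1.17, adjusted p = 4.24e-12, and 0.0408 with an estimated correlation). CDX1, the member called, had no count in E7 and stood at 1.08 ± 0.17 CPM in WNT (adjusted p = 0.0407). EOMES, which specifies mesendoderm, differed by 7.43 (SE 1.39, adjusted p = 0.0684) and was called with the block (adjusted p = 0.000481). TBXT differed by 3.80 (SE 1.28, adjusted p = 0.566) and was not called with either. Of 12 BMP targets, 1 rose (2 adjusted over the list alone), ID2 by 1.23 (SE 0.20), and the list lay higher (median 0.69, adjusted p = 7.19e-05, and 0.0418 with an estimated correlation). None of 23 pluripotency genes was called, also when adjusted over the list alone (0), and that list showed no shift (adjusted p = 0.914), with a median of -0.01, a mean of 0.03 and the test's direction down. NANOG differed by 0.86 (SE 0.33, adjusted p = 0.737), called with the block (adjusted p = 0.0194), and POU5F1 by 0.23 (SE 0.18, adjusted p = 1). Of 14 definitive endoderm and anterior streak genes, 1 fell (SHISA2; 1 adjusted over the list alone), with no shift of the list (adjusted p = 0.374, median 0.02, mean -0.20, direction down). With the block, 5 streak genes and 3 BMP targets rose, and 1 pluripotency gene rose and 1 fell. The Wnt target, streak and BMP lists also lay higher with the block and the preset correlation (adjusted p = 2.9e-11, 1.03e-07 and 0.000247). With the block and an estimated correlation, none of these 3 calls held (adjusted p = 0.0533, 0.167 and 0.12). HOX genes were not called (0 of 8, with 2 higher adjusted over the list alone and 2 with the block). Their list lay higher (median 2.34, and 0.10 with 4 members at 0 counts bounded; adjusted p = 0.00177; adjusted p = 0.0981 with an estimated correlation). Mesenchymal transition genes (0 of 14 called, 0 adjusted over the list alone, 1 higher with the block) also lay higher (adjusted p = 0.00495; adjusted p = 0.293 with an estimated correlation). So did S phase genes (0 of 16 called, 0 adjusted over the list alone; median 0.15, adjusted p = 0.0462; adjusted p = 0.402 with an estimated correlation). Activin and Nodal targets lay higher (1 of 13 rose, 2 higher and 1 lower adjusted over the list alone; adjusted p = 0.049; adjusted p = 0.449 with an estimated correlation), but not with the block (adjusted p = 0.191; 1 higher and 1 lower). Neuroectoderm genes lay lower (0 of 14 called, 0 adjusted over the list alone; median -0.33, adjusted p = 0.0211; adjusted p = 0.323 with an estimated correlation), but not with the block (adjusted p = 0.0544; 1 lower). The stress list passed with the block alone (adjusted p = 0.019, against 0.0771 without it).

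In all, 76 genes were called, 65 higher and 11 lower. With the replicate block the count was 414 (259 and 155), with the DESeq2 Wald test 255, with the stricter filter 49 and with the compared groups alone 6. Leaving out E7 replicate 1 or E7 replicate 2 left 9 calls each, WNT replicate 1 left 23 and WNT replicate 2 left 21.

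The second question was what CPI-203 alone changed in E7 medium at 24 h, from 1 library against 2. That library is replicate 2 and E7 holds both replicates, so values without the block carry part of the difference between replicates. The same holds for WNT_CPI against E7_CPI below. NANOG, a core factor of the pluripotent state, fell by 6.82 (SE 0.61, adjusted p = 0.000285), from 92.2 ± 29.0 CPM in E7 to 0.812 CPM. The other large falls were in TRIML2 (-7.04, SE 0.52), IDO1 (-6.32, SE 0.85), D21S2088E (-6.09, SE 0.58), TRDN (-5.81, SE 0.67) and the noncoding RNA LINC00678 (-5.48, SE 0.39). The histone gene H2BC5 rose by 5.27 (SE 0.26, adjusted p = 2.51e-05), from 3.59 ± 0.63 to 138 CPM, and the histone genes H3C14 by 5.24 (SE 0.46) and H4C15 by 5.07 (SE 0.26). TBX10 (5.42, SE 0.38), VGF (5.23, SE 0.84) and ZCCHC12 (4.99, SE 0.67) also rose.

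Among 14 genes raised by BET inhibition elsewhere, 13 rose and 1 fell, and as many adjusted over the list alone (13 and 1). The list lay higher (median 2.57, adjusted p = 2.58e-10, and 0.0133 with an estimated correlation). It includes H2BC12 (4.25, SE 0.30), H4C8 (4.90, SE 0.45) and ZMYND8, the member that fell (-3.12, SE 0.25). HEXIM1, an inhibitor of the elongation factor P-TEFb, rose by 1.81 (SE 0.19, adjusted p = 0.000452), and BRD2, itself a BET protein, by 1.01 (SE 0.17). Among 13 BET and P-TEFb genes, 2 rose and 0 fell (2 and 0 adjusted over the list alone), and the list did not shift (median 0.01, adjusted p = 0.403). BRD3 differed by -0.00 (SE 0.29) and was not called. Of 11 genes lowered by BET inhibition elsewhere, 3 rose and 1 fell (3 and 3 adjusted over the list alone), without a shift of the list (median -0.63, adjusted p = 0.685). MYC, a growth regulator that falls under BET inhibition in many blood cancers, rose by 2.36 (SE 0.54, adjusted p = 0.0155) here, RUNX1 rose by 2.22 (SE 0.55) and LMO2 by 1.44 (SE 0.43), while E2F2 fell by 3.39 (SE 0.35). With the block, 4 BET and P-TEFb genes rose and 1 fell, and 3 genes lowered by BET inhibition elsewhere rose and 4 fell. The list raised by BET inhibition was not called with the block and an estimated correlation (adjusted p = 0.0533).

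Of 23 pluripotency genes, 15 fell and 1 rose (17 and 1 adjusted over the list alone). Those that fell include USP44 (-3.36, SE 0.28), VRTN (-3.29, SE 0.32), DPPA4 (-2.03, SE 0.20) and POU5F1 (-1.08, SE 0.24, adjusted p = 0.0128). The list lay lower (median -1.62, adjusted p = 3.39e-08), a call lost with an estimated correlation (adjusted p = 0.212 with an estimated correlation). SOX2 differed by 0.41 (SE 0.36) and was not called. Of 14 mesenchymal transition genes, 4 rose and 1 fell (6 and 1 adjusted over the list alone). SNAI2 (4.97, SE 0.57), VIM (3.95, SE 0.48) and CDH2 (2.41, SE 0.43) rose, and MMP14 fell by 2.36 (SE 0.25). The list lay higher (median 0.67, adjusted p = 0.0195; adjusted p = 0.366 with an estimated correlation). With the block it was not called (adjusted p = 0.102), with 8 members higher and 2 lower. Of 19 cholesterol synthesis genes, 6 rose and 0 fell (9 and 0 adjusted over the list alone), among them INSIG1 (2.06, SE 0.30) and MVD (1.25, SE 0.21). That list lay higher (adjusted p = 0.00734; adjusted p = 0.461 with an estimated correlation). With the block 11 of its members rose and 1 fell. Immediate early genes (2 of 14 rose, 7 adjusted over the list alone; ATF3 by 1.54, SE 0.31) lay higher too (adjusted p = 0.0222; adjusted p = 0.417 with an estimated correlation), but not with the block (adjusted p = 0.0676; 8 members higher and 2 lower). BMP targets lay higher (3 of 12 rose, 3 adjusted over the list alone; GREM1 by 3.73, SE 0.42; adjusted p = 0.0195, and adjusted p = 0.191 with an estimated correlation), but not with the block (adjusted p = 0.137; 4 members higher and 1 lower). Of 13 Activin and Nodal targets, 3 fell (3 adjusted over the list alone), namely INHBA (-4.88, SE 0.78), SKIL (-4.20, SE 0.86) and FOXH1 (-4.05, SE 0.58), with no shift of the list (adjusted p = 0.25). Among canonical Wnt targets, AXIN2 fell by 1.77 (SE 0.29) and CCND1 fell by 1.80 (SE 0.34), while TNFRSF19 rose by 3.49 (SE 0.38) and NKD1 by 0.95 (SE 0.21); 3 of 14 rose and 2 fell (3 and 3 adjusted over the list alone). With the block, 5 Wnt targets rose and 4 fell, and 1 Activin and Nodal target rose and 4 fell.

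In all, 3121 genes were called, 1467 higher and 1654 lower, and 7834 with the block. Scaling by library totals alone moved the median of all genes from -0.054 to -0.145 in this comparison. Without E7 replicate 1 the count was 1686 and without E7 replicate 2 it was 1736. EOMES (3.23, SE 1.51, adjusted p = 0.177) and LEF1 (1.13, SE 0.65, adjusted p = 0.275) were called with the block alone (adjusted p = 0.0145 and 0.0273).

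The third question was what CPI-203 changed in Wnt3a-treated cells at 24 h, with 2 libraries per group. NANOG fell by 7.04 (SE 0.44, adjusted p = 1.68e-05), from 168 ± 42 CPM in WNT to 1.27 ± 0.066 CPM in WNT_CPI, and falls of like size were seen in LINC00678 (-7.13, SE 0.31), LINC00458 (-7.01, SE 1.05), TRDN (-6.74, SE 0.51), TRIML2 (-6.54, SE 0.37) and APELA, a ligand made by pluripotent cells (-6.47, SE 0.58). H2BC5 rose by 5.51 (SE 0.24, adjusted p = 7.65e-06), the neuronal gene STMN2 by 5.23 (SE 0.64), TBX10 by 4.97 (SE 0.36), CLSTN2 by 4.96 (SE 0.36), H3C14 by 4.91 (SE 0.43) and IER5L by 4.90 (SE 0.64). HEXIM1 rose by 1.96 (SE 0.17), from 77.8 ± 11.1 to 303 ± 11 CPM. MYC differed by 1.35 (SE 0.46, adjusted p = 0.0572) and was called with the block (adjusted p = 0.00176).

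Again 13 of 14 genes raised by BET inhibition elsewhere rose and 1 fell (13 and 1 adjusted over the list alone), with a median of 2.32 (adjusted p = 1.02e-09, and 0.0133 with an estimated correlation). With the block and an estimated correlation this list was not called (adjusted p = 0.0533). Of 23 pluripotency genes, 17 fell and 1 rose (18 and 1 adjusted over the list alone; median -1.86, adjusted p = 1.21e-09; adjusted p = 0.185 with an estimated correlation). VRTN (-3.61, SE 0.24), DPPA4 (-2.95, SE 0.16), ZSCAN10 (-2.65, SE 0.18) and POU5F1 (-1.31, SE 0.19) were among those that fell. Canonical Wnt targets were not lower: 5 of 14 rose and 0 fell (5 and 0 adjusted over the list alone). LGR5 rose by 4.92 (SE 1.34), TNFRSF19 by 4.40 (SE 0.36), NKD1 by 1.85 (SE 0.18) and LEF1 by 1.63 (SE 0.53). Their list lay higher (median 0.72, adjusted p = 0.0086; adjusted p = 0.212 with an estimated correlation). SP5 (-0.01, SE 0.49), AXIN2 (0.25, SE 0.22) and EOMES (0.16, SE 0.96) were not called with or without the block. NODAL differed by -2.84 (SE 1.05, adjusted p = 0.0731) and was called with the block (adjusted p = 0.0254).

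Neuroectoderm genes rose in 4 of 14 cases, with 0 lower (4 and 0 adjusted over the list alone). LHX2 rose by 3.02 (SE 0.51), POU3F2 by 2.80 (SE 0.46), ZIC1 by 1.83 (SE 0.57) and NES by 1.17 (SE 0.15). That list lay higher (median 1.32, adjusted p = 0.00562; adjusted p = 0.253 with an estimated correlation). Of 15 epithelial genes, which hold cells together in a sheet, 7 fell and 0 rose (7 and 0 adjusted over the list alone), among them ESRP1 (-2.10, SE 0.13), GRHL2 (-2.03, SE 0.15) and EPCAM (-1.34, SE 0.13), without a shift of the list (adjusted p = 0.112). Of 14 mesenchymal transition genes, 6 rose and 1 fell (6 and 1 adjusted over the list alone; SNAI2 by 4.95, SE 0.53; list adjusted p = 0.058). Of 16 p53 targets, 6 rose and 1 fell (6 and 1 adjusted over the list alone; median 0.57, adjusted p = 0.0187; adjusted p = 0.416 with an estimated correlation), TNFRSF10B by 0.88 (SE 0.14) and SESN1 by 1.23 (SE 0.24). Of 14 definitive endoderm and anterior streak genes, 3 rose and 1 fell (3 and 1 adjusted over the list alone), without a shift of the list (adjusted p = 0.52). The endoderm factor FOXA1 rose by 4.48 (SE 1.09) and FOXA3 fell by 2.69 (SE 0.52, adjusted p = 0.00459). CDX2 rose by 3.77 (SE 0.86) and HAND1 by 6.60 (SE 1.11), while KDR fell by 2.70 (SE 0.42) and TBX6 fell by 1.87 (SE 0.25). Streak and early mesoderm genes went both ways (5 higher and 2 lower of 19; 5 and 3 adjusted over the list alone). So did FGF and MAPK targets (3 and 3 of 14; 4 and 3 adjusted over the list alone), trophoblast and amnion genes (2 and 3 of 9; 2 and 3 adjusted over the list alone), fibroblast genes (1 and 4 of 9; 2 and 4 adjusted over the list alone) and S phase genes (2 and 4 of 16; 3 and 4 adjusted over the list alone), and none of these lists shifted (adjusted p = 0.729, 0.996, 0.965, 0.74 and 0.656). For the trophoblast list the median (-0.15) and mean (-0.33) were negative and the test's direction up, and for the fibroblast list the median was 0.03, the mean -0.02 and the direction down. Ribosome biogenesis (1 of 19 rose, 0 adjusted over the list alone; adjusted p = 0.246) and hypoxia and glycolysis (1 rose and 2 fell of 15, and as many adjusted over the list alone, 1 and 2; adjusted p = 0.819) did not shift. Stress of unfolded proteins and amino acids (0 rose and 3 fell of 12; 1 and 5 adjusted over the list alone; adjusted p = 0.256) and G2 and M phase genes (0 rose and 1 fell of 18; 0 and 0 adjusted over the list alone; adjusted p = 0.864) did not shift. With the block, 7 neuroectoderm genes rose, 4 epithelial genes rose and 7 fell, and 7 mesenchymal transition genes rose and 2 fell. The p53 targets then had 12 rises and 1 fall, the streak list 7 and 4, the FGF and MAPK list 5 and 5, the fibroblast list 2 and 4 and the S phase list 3 and 8. Ribosome biogenesis had 9 and 2, hypoxia and glycolysis 4 and 3, the stress list 2 and 6 and the G2 and M list 3 and 5.

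In all, 4722 genes were called, 1941 higher and 2781 lower, and 9417 with the block. Leaving out WNT replicate 1, WNT replicate 2, WNT_CPI replicate 1 or WNT_CPI replicate 2 gave 2965, 2808, 2853 and 2725. Of the genes called for CPI-203 without Wnt3a, 1290 were called higher and 1514 lower with it too, against 160 and 258.5 for independent sets, and 2 were called in opposite directions. These comparisons share no library.

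**Figure D2:**
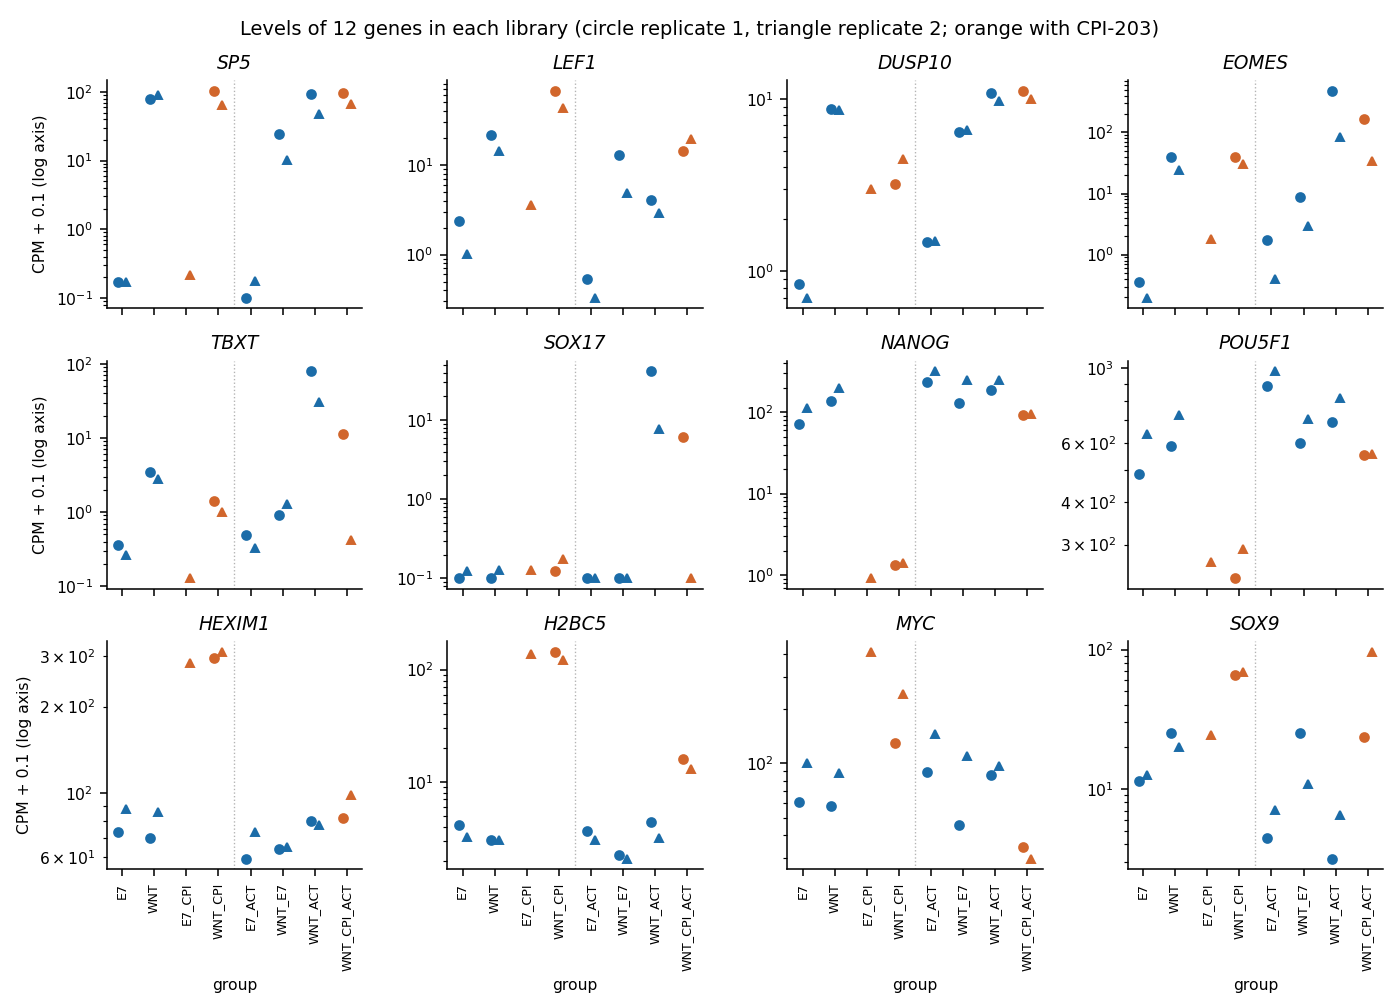
Level of 12 genes in each library, as CPM plus 0.1 on a log axis, by group, with a circle for replicate 1 and a triangle for replicate 2, orange where CPI-203 was given and 24 h groups left of the dotted line. NANOG stands at 0.812 CPM in E7_CPI and at 92.7 ± 1.3 CPM in WNT_CPI_ACT; the points are single libraries, with no error bars.

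The next question was whether CPI-203 changed the response to Wnt3a. With the inhibitor present, Wnt3a (WNT_CPI against the 1 library of E7_CPI) still raised FST by 4.36 (SE 0.58), SP8 by 4.12 (SE 0.52), the Wnt secretion factor WLS by 3.92 (SE 0.41) and CCND1 by 3.73 (SE 0.38). AXIN2, a feedback target of the pathway, rose by 3.07 (SE 0.32, adjusted p = 0.0105) and NKD1 by 2.94 (SE 0.25). SP5 stood at 0.112 CPM in E7_CPI (4 counts) and at 84.3 ± 28.1 CPM in WNT_CPI. Of 14 canonical Wnt targets, 6 rose and 0 fell (9 and 0 adjusted over the list alone; median 2.82, adjusted p = 8.51e-31, and 0.00321 with an estimated correlation). LEF1 differed by 3.98 (SE 0.80, adjusted p = 0.237) and was called with the block (adjusted p = 0.00751). HOX genes were not called (0 of 8, and 2 higher adjusted over the list alone), but their list lay higher (median 2.80, and 2.14 with members at 0 counts bounded; adjusted p = 2.37e-08, and 0.0176 with an estimated correlation). With the block and an estimated correlation, the Wnt target list was still called (adjusted p = 0.0277) and the HOX list was not (adjusted p = 0.101). The HOX list had also lain higher for Wnt3a without the inhibitor, as given above. Streak and early mesoderm genes (0 of 19 called, 3 higher adjusted over the list alone, 3 higher with the block) lay higher (median 1.60, adjusted p = 1.01e-07; adjusted p = 0.0947 with an estimated correlation). S phase genes (0 of 16 called, 0 adjusted over the list alone, 1 higher with the block) lay higher (adjusted p = 0.000239; adjusted p = 0.185 with an estimated correlation). BMP targets (0 of 12 called, 0 adjusted over the list alone) lay higher as well (adjusted p = 0.049; adjusted p = 0.25 with an estimated correlation). Epithelial genes (0 of 15 called, 0 adjusted over the list alone, 1 lower with the block) lay lower (median -0.40, adjusted p = 2.93e-05; adjusted p = 0.323 with an estimated correlation). The stress list (0 of 12 called, 2 lower adjusted over the list alone, 1 lower with the block) lay lower too (adjusted p = 9.22e-05; adjusted p = 0.191 with an estimated correlation). Cholesterol synthesis genes (0 of 19 called, 0 adjusted over the list alone; adjusted p = 0.00094; adjusted p = 0.373 with an estimated correlation) and trophoblast genes (0 of 9 called, 0 adjusted over the list alone; adjusted p = 0.00903; adjusted p = 0.283 with an estimated correlation) were also lower as lists. Pluripotency genes (0 of 23 called, 1 lower adjusted over the list alone, 1 lower with the block) lay lower (adjusted p = 0.00423; adjusted p = 0.461 with an estimated correlation), but not with the block (adjusted p = 0.0798). Immediate early genes (0 of 14 called, 0 adjusted over the list alone) lay lower (adjusted p = 0.0276; adjusted p = 0.435 with an estimated correlation), but not with the block (adjusted p = 0.239). With the block alone, the G2 and M, p53 and mesenchymal transition lists lay higher (adjusted p = 0.001, 0.00554 and 0.046), against 0.131, 0.228 and 0.115 without it.

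In that comparison 15 genes rose and 0 fell. The DESeq2 Wald test called 82 genes (64 higher, 18 lower) and the block 95 (72 higher, 23 lower), all at an adjusted p under 0.05. At an unadjusted p under 0.05, genes in both directions numbered 576 with edgeR, 572 with the DESeq2 Wald test and 1285 with the block. Unchanged genes alone would give a share of 0.05 of the 17793 tested, above the numbers without the block and below that with it. Without WNT_CPI replicate 1 the count was 2. Of the 76 genes called for Wnt3a alone, 72 had the same sign with the inhibitor and 11 were called in both, against 0.05 for independent sets, namely DSP, ERICH2, FST, NKD1, RNF43, SALL3, SP5, SP8, TCF7, TNFRSF11B and WLS. With the block 54 of 414 were, and with the DESeq2 Wald test 51 of 255. The median change of the 65 genes that rose was 2.29 without and 1.36 with CPI-203. Over the genes that rose for Wnt3a with the block, the medians were 1.32 and 0.54. Over those that rose with the DESeq2 Wald test they were 1.79 and 0.89. The interaction itself, tested over all genes, called 1 gene. DUSP10, a phosphatase of stress kinases, was named after its values were seen: Wnt3a changed it by 3.67 without and 0.38 with CPI-203 (difference -3.29, SE 0.33, adjusted p = 0.0392). Leaving out any 1 library of E7, WNT or WNT_CPI left 0 calls, as did the fit on the compared groups alone. At an adjusted p under 0.05 and with every library in, the DESeq2 Wald test called 16 genes. At an unadjusted p under 0.05, edgeR had 303 and the DESeq2 Wald test 299. Both are below a share of 0.05 of the genes tested, which unchanged genes alone would give. The block called 7 at an adjusted p under 0.05, also named after their values were seen: DUSP10, RGMB, RGMB-AS1, GRB14 and SLFN12 were lower with the inhibitor, and CCND1 and HCN4 higher, CCND1 by 2.60 (adjusted p = 0.0101 with the block). Adjusted over the 76 Wnt3a genes alone, 28 differed, 25 of them with a difference opposite in sign to the Wnt3a effect. These genes were chosen on the E7 and WNT libraries that the interaction shares, which favours that direction and also a smaller median with CPI-203. Canonical Wnt targets had a higher Wnt3a response with CPI-203 as a list (median 0.90, adjusted p = 2.67e-06, and 0.0418 with an estimated correlation; 0 called, and 3 higher adjusted over the list alone). Of E7_CPI only replicate 2 was fitted, so the interaction without the block carries part of the difference between replicates. With the block that list lay higher with the preset correlation (adjusted p = 0.000391; 1 called), but was not called with an estimated one (adjusted p = 0.123). Of the other lists, 7 passed with the preset correlation in the interaction and none with an estimated one, with 0 members called in each, also adjusted over the list alone (0). Epithelial genes had a lower response (median -0.27, adjusted p = 0.000117; adjusted p = 0.342 with an estimated correlation) and neuroectoderm genes a higher one (median 0.47, adjusted p = 0.000959; adjusted p = 0.191 with an estimated correlation). These 2 calls held with the block and the preset correlation (adjusted p = 0.000274 and 0.00218). The next 5 did not. Pluripotency genes had a lower response (median -0.31, adjusted p = 0.00914; 0.106 with the block; adjusted p = 0.515 with an estimated correlation), as did immediate early genes (median -0.68, adjusted p = 0.0183; 0.133 with the block; adjusted p = 0.413 with an estimated correlation). Cholesterol synthesis genes (median -0.16, adjusted p = 0.029; 0.0752 with the block; adjusted p = 0.575 with an estimated correlation) and the stress list (median -0.30, adjusted p = 0.0329; 0.123 with the block; adjusted p = 0.416 with an estimated correlation) were lower too. For HOX genes the median was -0.10, the mean 1.04 and the direction up (adjusted p = 0.0462; 0.239 with the block; adjusted p = 0.25 with an estimated correlation). With the block and the preset correlation, the S phase and p53 lists had a higher response (adjusted p = 0.00186 and 0.0465), against 0.122 and 0.455 without it. NANOG (-0.22, SE 0.60), MYC (-1.01, SE 0.71), EOMES (-3.07, SE 1.81) and AXIN2 (2.02, SE 0.36) were not called in the interaction.

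At 48 h, the question was what Wnt3a on day 1 changed in cells given Activin A on day 2. EOMES rose by 8.18 (SE 1.33, adjusted p = 0.0171), from 0.972 ± 0.943 CPM in E7_ACT to 283 ± 282 CPM in WNT_ACT, and TBXT, the mesoderm factor brachyury, by 7.47 (SE 1.39, adjusted p = 0.0284). The receptor gene APLNR rose by 5.53 (SE 0.58), GAD1 by 6.64 (SE 0.81), MAGEB17 by 4.93 (SE 0.92) and GMPR by 4.84 (SE 1.05). FGF17 stood at 0.0495 CPM (2 counts in each library) in E7_ACT and at 138 ± 94 CPM in WNT_ACT (adjusted p = 0.0186). TMT1A (-2.74, SE 0.32), HESX1 (-2.39, SE 0.48), CCDC80 (-2.31, SE 0.27), GPR176 (-2.26, SE 0.49), PCSK5 (-2.20, SE 0.17) and RND3 (-2.19, SE 0.24) fell.

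Of 19 streak and early mesoderm genes, 5 rose and 0 fell (10 and 0 adjusted over the list alone; median 2.18, adjusted p = 2.58e-10, and 0.0458 with an estimated correlation). Of 14 canonical Wnt targets, 6 rose and 0 fell (11 and 0 adjusted over the list alone; median 1.66, adjusted p = 4.24e-12, and 0.0135 with an estimated correlation). APCDD1 rose by 4.45 (SE 0.54), AXIN2 by 1.79 (SE 0.23) and LEF1 by 3.33 (SE 0.64). Of 14 definitive endoderm and anterior streak genes, 1 rose (PRDM1, 4.17, SE 0.73) and 0 fell (7 and 0 adjusted over the list alone; 7 and 0 with the block). The list lay higher (median 4.03, adjusted p = 2.15e-06; adjusted p = 0.293 with an estimated correlation). The endoderm and anterior streak factors SOX17, GSC, MIXL1 and FOXA2 were called with the block alone (adjusted p = 0.00258, 0.00121, 0.00696 and 0.00269). Without it their adjusted p was 0.0916, 0.0505, 0.0587 and 0.0761. The Wnt antagonist DKK1 was also called with the block alone (7.11, SE 1.77, adjusted p = 0.078; 0.017 with the block). SOX17 had no count in E7_ACT and stood at 24.6 ± 24.0 CPM in WNT_ACT, and MIXL1 at 4.28 ± 0.42 and 450 ± 488 CPM. Between replicates, endoderm genes were higher in WNT_ACT replicate 1 than in replicate 2 by a median of 1.56. Of 23 pluripotency genes, 3 fell and 1 rose (5 and 1 adjusted over the list alone), with TERF1 at -1.51 (SE 0.22) and DNMT3B at -0.94 (SE 0.16) among those that fell. The list lay lower (median -0.52, adjusted p = 7.95e-05; adjusted p = 0.332 with an estimated correlation). NANOG differed by -0.34 (SE 0.33) and POU5F1 by -0.31 (SE 0.18, adjusted p = 0.643), which was called with the block (adjusted p = 0.0376). With the block 10 streak genes and 11 Wnt targets rose, and 1 pluripotency gene rose and 11 fell. Neither the streak list nor the Wnt target list was called with the block and an estimated correlation (adjusted p = 0.191 and 0.0789).

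In all, 379 genes were called, 260 higher and 119 lower, 2024 with the block, 962 with the DESeq2 Wald test and 0 with the compared groups alone. Without E7_ACT replicate 1 the count was 30, without E7_ACT replicate 2 it was 72, and without WNT_ACT replicate 1 it was 57. Of the genes called for Wnt3a at 24 h, 43 were called higher and 5 lower here too, against 0.9 and 0.1 for independent sets, with 0 opposite calls; these comparisons share no library.

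Activin A on day 2 after Wnt3a (WNT_ACT against WNT_E7) raised APLNR by 4.27 (SE 0.54, adjusted p = 0.0351), NTS, the neurotensin gene, by 2.94 (SE 0.34), RNF19A by 2.34 (SE 0.34), BACE2 by 2.31 (SE 0.25), AP3B2 by 2.10 (SE 0.30) and FAM110B by 2.02 (SE 0.19). LRAT (-2.12, SE 0.21), JADE1 (-1.32, SE 0.17) and LRRN1 (-1.11, SE 0.14) fell. The definitive endoderm list lay higher (median 3.98, adjusted p = 1.31e-11; adjusted p = 0.176 with an estimated correlation), with 0 of 14 members called (8 higher adjusted over the list alone, 8 with the block). CER1, a secreted antagonist from anterior endoderm, stood at 0.387 ± 0.547 CPM in WNT_E7 and 1048 ± 1309 CPM in WNT_ACT, from 4650 and 76881 counts in its libraries (adjusted p = 0.199; 0.0133 with the block). EOMES (5.64, SE 1.17, adjusted p = 0.0961), TBXT (5.78, SE 1.26, adjusted p = 0.107), FOXA2 (6.23, SE 1.63, adjusted p = 0.161) and SP5 (2.03, SE 0.51, adjusted p = 0.143) were called with the block alone (adjusted p = 0.000898, 0.00709, 0.00793 and 0.00415). So were GSC, MIXL1, SOX17 and SOX2 (adjusted p = 0.00378, 0.00879, 0.00607 and 0.0415, against 0.109, 0.0858, 0.162 and 0.597 without it), with SOX2 lower. Of 19 streak genes 1 rose, APLNR, and 0 fell (9 and 0 adjusted over the list alone; median 3.12, and 2.29 with a member at 0 counts bounded; adjusted p = 1.74e-09; adjusted p = 0.057 with an estimated correlation). Of 13 Activin and Nodal targets 0 were called (5 higher and 1 lower adjusted over the list alone; median 0.86, adjusted p = 0.00254; adjusted p = 0.283 with an estimated correlation). With the block 9 streak genes rose, and 3 Activin and Nodal targets rose and 1 fell. Mesenchymal transition genes and genes raised by BET inhibition elsewhere lay higher by camera (adjusted p = 5.24e-05 and 0.00513). Pluripotency genes lay lower (adjusted p = 0.000415). Fibroblast genes and canonical Wnt targets lay higher (adjusted p = 0.00972 and 0.00903), but not with the block (0.0845 and 0.0617). None of these calls held with an estimated correlation. In all, 22 genes were called, 19 higher and 3 lower, 1130 with the block, 571 with the DESeq2 Wald test and 0 with the compared groups alone. Without WNT_ACT replicate 1 or WNT_E7 replicate 1 the count was 0, without WNT_E7 replicate 2 it was 2, and without WNT_ACT replicate 2 it was 84.

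The question at the end of the course was what CPI-203 on day 1 left behind on day 2 (WNT_CPI_ACT against WNT_ACT). The tight junction gene CLDN7 fell by 5.26 (SE 0.65, adjusted p = 0.00492), LAD1 by 3.93 (SE 0.37), CRYBG1 by 3.55 (SE 0.39), PPP2R2C by 3.30 (SE 0.30), ANXA3 by 3.17 (SE 0.43) and the growth factor gene FGF19 by 3.17 (SE 0.33). STMN2 rose by 6.35 (SE 0.69, adjusted p = 0.00285), from 0.784 ± 0.201 to 64.1 ± 51.8 CPM, ISLR2 by 5.75 (SE 0.78), GBX2 by 4.99 (SE 0.65), SHISA3 by 3.80 (SE 0.54), SOX9, a neural crest and chondrocyte factor, by 3.67 (SE 0.68) and LHFPL6 by 3.38 (SE 0.64).

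Of 15 epithelial genes, 9 fell and 0 rose (9 and 0 adjusted over the list alone): GRHL2 by 2.45 (SE 0.15), CDH1, the epithelial cadherin, by 1.93 (SE 0.18), EPCAM by 1.58 (SE 0.14) and ESRP1 by 1.56 (SE 0.13). The list lay lower (median -1.51, adjusted p = 1.02e-09; adjusted p = 0.185 with an estimated correlation). Of 14 mesenchymal transition genes, 2 rose, SNAI2 by 3.43 (SE 0.50) and VIM by 3.34 (SE 0.43), and 1 fell (3 and 2 adjusted over the list alone), with no shift of the list (adjusted p = 0.501, median -0.03, mean 0.64, direction up). Of 8 HOX genes, 1 rose (6 adjusted over the list alone). The HOX list lay higher (median 5.01, and 3.22 with members at 0 counts bounded; adjusted p = 1.9e-07, and 0.0222 with an estimated correlation). Of 14 definitive endoderm genes 0 were called (1 lower adjusted over the list alone, 10 lower with the block), and the list lay lower (median -2.95, adjusted p = 2.85e-05; adjusted p = 0.332 with an estimated correlation). SOX17 (-3.03, SE 1.60), GSC (-4.42, SE 1.46), FOXA2 (-3.26, SE 1.39), MIXL1 (-3.70, SE 1.32), CER1 (-3.92, SE 2.20), TBXT (-3.24, SE 1.098) and EOMES (-1.49, SE 0.97) were lower in both replicates and called with the block alone (adjusted p = 0.015, 0.00318, 0.0135, 0.0221, 0.0332, 0.0099 and 0.036). Without it their adjusted p was 0.428, 0.142, 0.267, 0.174, 0.458, 0.152 and 0.546. SOX17 had 261 counts in WNT_CPI_ACT replicate 1 and 0 in replicate 2, and endoderm genes were higher in replicate 1 of that group by a median of 3.93. With the block, 5 mesenchymal transition genes rose and 4 fell, and 6 HOX genes rose. The HOX list was not called with the block and an estimated correlation (adjusted p = 0.101).

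Of 13 Activin and Nodal targets, FST rose by 2.82 (SE 0.39) and PMEPA1 fell by 2.43 (SE 0.45), 1 in each direction (1 and 6 adjusted over the list alone), and the list lay lower (median -1.33, adjusted p = 0.00601; adjusted p = 0.323 with an estimated correlation). NODAL differed by -4.55 (SE 1.12, adjusted p = 0.059) and LEFTY1 by -5.17 (SE 1.51, adjusted p = 0.101), both called with the block (adjusted p = 0.00854 and 0.00893). Of 23 pluripotency genes, 1 fell (2 higher and 2 lower adjusted over the list alone; list adjusted p = 0.211). NANOG differed by -1.24 (SE 0.33, adjusted p = 0.0768), MYC by -1.51 (SE 0.47, adjusted p = 0.117), POU5F1 by -0.44 (SE 0.18, adjusted p = 0.253), SOX2 by 0.75 (SE 0.30, adjusted p = 0.236) and LEF1 by 2.32 (SE 0.55, adjusted p = 0.0512), all called with the block (adjusted p = 0.000829, 0.00396, 0.0054, 0.00919 and 0.00137). HEXIM1 (0.19, SE 0.16) and BRD2 (0.06, SE 0.15) were not called. H2BC5 rose by 1.97 (SE 0.21), 1 of 14 genes raised by BET inhibition elsewhere (1 adjusted over the list alone; list median 0.35, adjusted p = 0.00586; adjusted p = 0.132 with an estimated correlation). Canonical Wnt targets showed 2 rises, RNF43 by 1.47 (SE 0.30) and TNFRSF19 by 1.94 (SE 0.34), and 1 fall, NOTUM by 2.53 (SE 0.47) (4 and 1 adjusted over the list alone), with no shift of the list (adjusted p = 0.393, median 0.19, mean -0.10, direction up). With the block, 1 Activin and Nodal target rose and 8 fell, 3 pluripotency genes rose and 4 fell, 4 Wnt targets rose and 2 fell, and 2 genes raised by BET inhibition elsewhere rose.

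In all, 648 genes were called, 179 higher and 469 lower, 3590 with the block, 1496 with the DESeq2 Wald test and 0 with the compared groups alone. Without WNT_ACT replicate 1 or WNT_ACT replicate 2 the count was 324 and 162, and without WNT_CPI_ACT replicate 1 or replicate 2 it was 413 and 136.

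**Figure D3:**
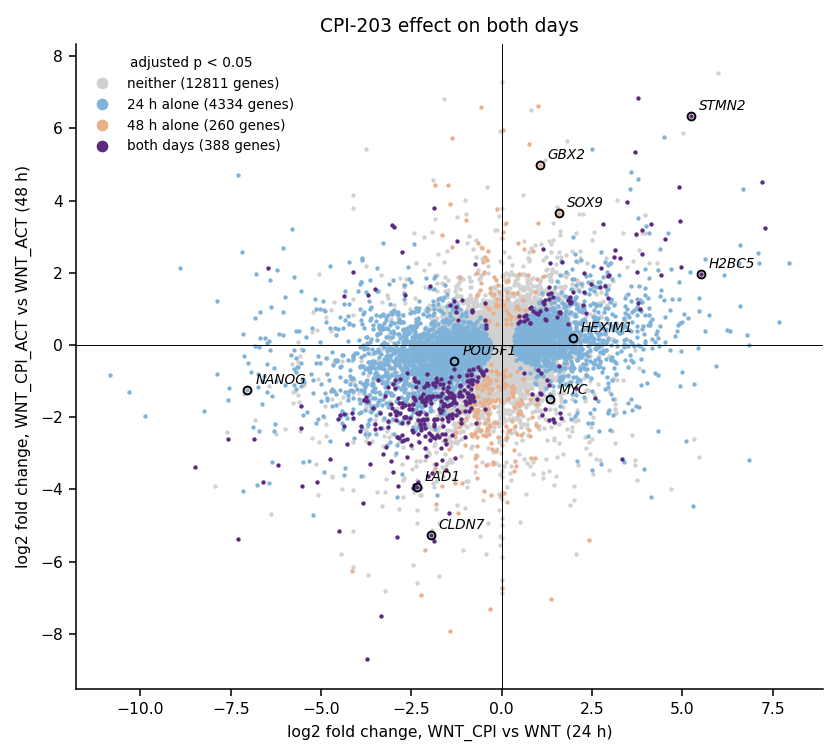
Log2 fold change of each gene for CPI-203 at 24 h (WNT_CPI against WNT, horizontal) and at 48 h (WNT_CPI_ACT against WNT_ACT, vertical), each point 1 gene, coloured by the comparison in which its adjusted p was under 0.05. NANOG lies at -7.04 on the first and -1.24 on the second day, HEXIM1 at 1.96 and 0.19.

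The effect of CPI-203 was compared between both days, a contrast added after the data were seen; Activin A, given on day 2 alone, and time cannot be told apart in it. Of the genes called at 24 h, 74 were called higher and 268 lower at 48 h too, against 19.5 and 73.3 for independent sets, and 46 in opposite directions. The difference itself called 1796 genes, with the effect of CPI-203 higher at 48 h in 1096 and lower in 700. Rises and falls below are in this difference of effects, not in levels. NANOG rose in this difference by 5.80 (SE 0.51, adjusted p = 0.000307), USP44 by 3.52 (SE 0.28), VRTN by 3.49 (SE 0.32) and DPPA4 by 2.98 (SE 0.21). In all, 13 of 23 pluripotency genes rose and 0 fell (15 and 1 adjusted over the list alone). HEXIM1 fell by 1.77 (SE 0.23), H2BC5 by 3.53 (SE 0.30), H2BC12 by 3.504 (SE 0.37) and BRD2 by 0.94 (SE 0.21). In all, 12 of 14 genes raised by BET inhibition elsewhere fell and 1 rose (12 and 1 adjusted over the list alone). MYC fell by 2.86 (SE 0.66, adjusted p = 0.0242). CDH1 fell by 2.37 (SE 0.25), ST14 by 2.79 (SE 0.48), CLDN7 by 3.29 (SE 0.79) and CDH3 by 1.38 (SE 0.30), and 4 of 15 epithelial genes fell in all (2 higher and 4 lower adjusted over the list alone). With the block 2 epithelial genes rose and 7 fell, and 19 pluripotency genes rose and 1 fell. DKK1, GSC and MIXL1 (effect lower at 48 h) and POU5F1 and SOX2 (effect higher) were called with the block alone (adjusted p = 0.0364, 0.017, 0.0372, 0.000334 and 0.0086, against 0.142, 0.136, 0.136, 0.0637 and 0.197 without it). With the block the count was 5923, with the DESeq2 Wald test 2721 and with the compared groups alone 886. Without WNT replicate 1 or replicate 2 it was 889 and 894, without WNT_CPI replicate 1 or replicate 2 1038 and 878, and without WNT_ACT replicate 1 1153.

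WNT_CPI_ACT was also set against E7_ACT, cells given Activin A alone. GAD1 rose by 7.12 (SE 0.82), STMN2 by 7.74 (SE 0.75), EOMES by 6.69 (SE 1.25, adjusted p = 0.00976) and APLNR by 6.28 (SE 0.60), while CLDN7 fell by 5.23 (SE 0.65), CRYBG1 by 4.54 (SE 0.41) and LEFTY1, a Nodal target, by 6.56 (SE 1.61). NANOG fell by 1.58 (SE 0.34), POU5F1 by 0.75 (SE 0.18) and MYC by 1.88 (SE 0.47). Of 8 HOX genes, 4 rose (7 adjusted over the list alone; median 7.30, and 3.72 with 7 members at 0 counts bounded; adjusted p = 4.04e-07, and 0.023 with an estimated correlation). Canonical Wnt targets (9 of 14 rose, 0 fell; 11 and 0 adjusted over the list alone; RNF43 by 2.91, SE 0.32) and genes raised by BET inhibition elsewhere (3 of 14 rose; 3 adjusted over the list alone; H1-2 by 1.27, SE 0.26) lay higher (adjusted p = 3.12e-07 and 0.000161, and 0.0374 and 0.0458 with an estimated correlation). Epithelial genes (10 of 15 fell, 10 adjusted over the list alone; adjusted p = 3.12e-07; adjusted p = 0.244 with an estimated correlation) and pluripotency genes (10 of 23 fell and 1 rose; 13 and 1 adjusted over the list alone; adjusted p = 8.77e-05; adjusted p = 0.332 with an estimated correlation) lay lower. With the block, 7 HOX genes rose, 10 Wnt targets rose and 1 fell, and 9 genes raised by BET inhibition elsewhere rose. Then 3 epithelial genes rose and 10 fell, and 1 pluripotency gene rose and 16 fell. By camera, streak and early mesoderm genes lay higher (6 of 19 rose and 0 fell, adjusted p = 7.95e-05). So did mesenchymal transition genes (7 of 14 rose and 0 fell, adjusted p = 0.0194), but not with the block (0.155). Activin and Nodal targets lay lower (1 of 13 rose and 4 fell, adjusted p = 0.00734). None of these calls held with an estimated correlation (0.191, 0.366 and 0.323). With the block and an estimated correlation, the HOX, Wnt target and BET lists were not called (adjusted p = 0.101, 0.119 and 0.119). TBXT (4.22, SE 1.25, adjusted p = 0.0613) and SOX17 (0 counts in E7_ACT, 2.996 ± 4.24 CPM, adjusted p = 0.107) were called with the block (adjusted p = 0.0165 and 0.0121). FOXA2 (3.59, SE 1.51, adjusted p = 0.182), GSC (4.30, SE 1.77, adjusted p = 0.173) and HEXIM1 (0.45, SE 0.16, adjusted p = 0.119) were too (adjusted p = 0.0413, 0.0405 and 0.00615). The SOX17 counts in WNT_CPI_ACT came from replicate 1 alone. The block assumes a difference between replicates that all groups share. Definitive endoderm genes differed by a median of 3.93 in WNT_CPI_ACT and -0.37 in E7_ACT. In all, 1894 genes were called, 771 higher and 1123 lower, 5695 with the block and 73 with the compared groups alone. Without E7_ACT replicate 1 or replicate 2 the count was 945 and 779, and without WNT_CPI_ACT replicate 1 or replicate 2 it was 1029 and 1100. Of the genes called in WNT_ACT against E7_ACT, 164 were called higher and 94 lower here too, against 11.3 and 7.5 for independent sets. These comparisons share both E7_ACT libraries, and the overlap with a separate E7_ACT library for each was not computed. In 20 simulations with no true change the mean overlap was 0; hardly any gene is called there, so this does not measure what shared controls add. Over 13976 genes the changes correlated at r = 0.683, and shared controls alone gave a mean r of 0.506 in the simulations. The covariance was 0.41 against 0.028 simulated. Part of the overlap and of the correlation may come from shared controls.

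Finally, the 48 h controls were set against the 24 h groups, where time and treatment cannot be told apart. In E7_ACT against E7, STOX2 rose by 4.66 (SE 0.74), NTS by 3.96 (SE 0.36, adjusted p = 0.00773), the matrix protease gene MMP9 by 3.94 (SE 0.47), the feedback inhibitors SMAD7 by 3.11 (SE 0.45) and SMAD6 by 3.11 (SE 0.51), and MMP2 by 1.297 (SE 0.13). PKDCC (-3.78, SE 0.53), INHBA (-3.31, SE 0.51), SEZ6 (-3.14, SE 0.46), IRX2 (-2.97, SE 0.34) and AXIN2 (-1.38, SE 0.22) fell. LEFTY1 stood at 0.144 ± 0.067 CPM in E7 and 309 ± 93 CPM in E7_ACT (adjusted p = 0.0756), NODAL at 1.58 ± 0.07 and 52.7 ± 15.9 CPM (adjusted p = 0.152), both called with the block (adjusted p = 0.00456 and 0.0298). NANOG (1.58, SE 0.34, adjusted p = 0.12) and POU5F1 (0.73, SE 0.18, adjusted p = 0.189) were called with the block too (adjusted p = 0.000877 and 0.00148). LEFTY2 (adjusted p = 0.114; 0.0149 with the block) was another, and LEF1 was lower (-2.26, SE 0.64, adjusted p = 0.278; 0.0449 with the block). Of 13 Activin and Nodal targets, 1 rose and 1 fell (7 and 1 adjusted over the list alone), and the list lay higher (median 1.52, adjusted p = 1.05e-05; adjusted p = 0.16 with an estimated correlation). Of 12 BMP targets 1 rose (5 adjusted over the list alone), with the list higher (median 0.85, adjusted p = 3.04e-06, and 0.0286 with an estimated correlation). With the block, 6 Activin and Nodal targets rose and 1 fell, and 5 BMP targets rose. The BMP list was not called with the block and an estimated correlation (adjusted p = 0.12). In all, 50 genes were called, 33 higher and 17 lower, 741 with the block, 349 with the DESeq2 Wald test and 12 with the compared groups alone. Without E7 replicate 1 or replicate 2 the count was 0, and without E7_ACT replicate 1 or replicate 2 it was 1 and 7. In WNT_E7 against WNT, a day after Wnt3a was taken away, edgeR called 0 genes, the DESeq2 Wald test 7 and the block 7, each at an adjusted p under 0.05. At an unadjusted p under 0.05 edgeR had 316 without the block and 1463 with it. A share of 0.05 of the genes tested, as unchanged genes alone would give, lies between these numbers. SP5 stood at 84.9 ± 9.0 CPM in WNT and 17.3 ± 10.2 CPM in WNT_E7 (change -2.30, SE 0.51, adjusted p = 1; 0.0394 with the block). Canonical Wnt targets lay lower as a list (median -0.54, and -0.46 with a member at 0 counts bounded; adjusted p = 1.21e-06, and 0.0411 with an estimated correlation; 0 of 14 called, 3 lower adjusted over the list alone). With the block 1 member fell, and with an estimated correlation as well the list was not called (adjusted p = 0.12).

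**Figure D4:**
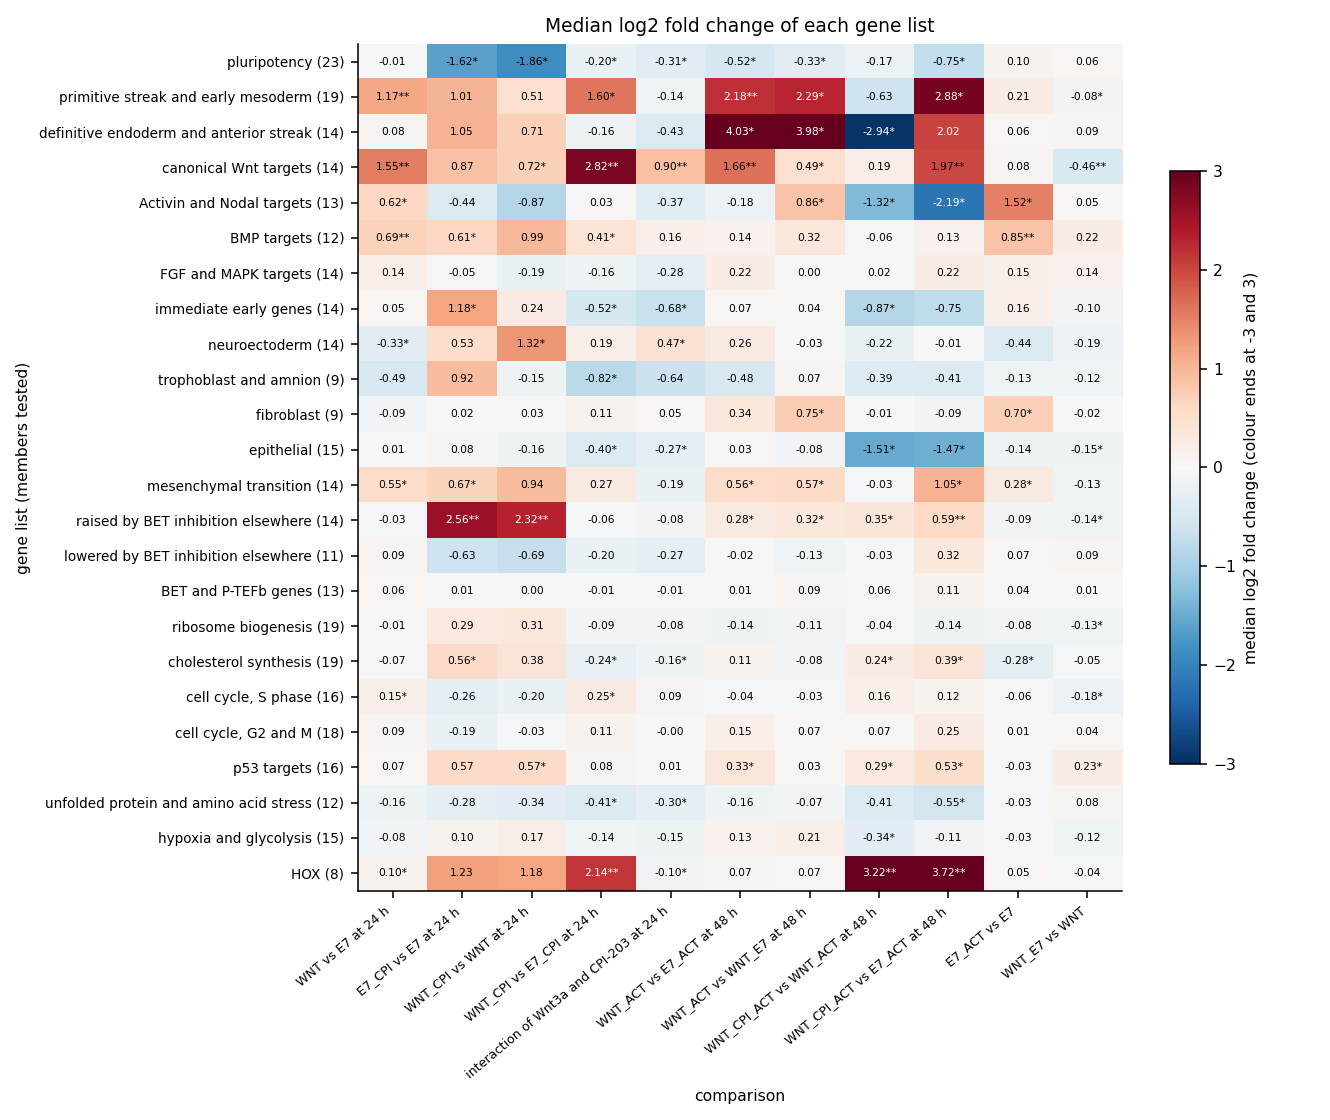
Median log2 fold change of each gene list (vertical, with the members tested) in each comparison (horizontal), with members at 0 counts in a group set to their bound and the colour scale ending at -3 and 3. A single star marks an adjusted camera p under 0.05 with the preset correlation, and a double star one that also held with an estimated correlation, 85 and 16 of 264 tests.

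The ATAC list held 313223 positions that covered 162.3 megabases, with a median width of 398 bp and a mean of 518 bp. Their build was assumed to be GRCh37. Widths ran from 112 to 18717 bp, 10.7% were at least 1000 bp wide and 0 overlapped the one before. As the list is combined over all samples, it gives no value per group, and the response of chromatin to Wnt3a, CPI-203 or Activin A was not analysed here.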

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

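The tests of explanations in this part, the difference of the CPI-203 effect between 48 h and 24 h and every use of the reordered E7_CPI column were chosen after the results were seen, while the interaction of Wnt3a and CPI-203 was not.

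The first result differed between groups: the response to Wnt3a differed by CPI-203 in 1 gene over all genes, DUSP10, by the interaction test. The second set differed between days: the effect of CPI-203 in Wnt3a-treated cells differed between 48 h and 24 h in 1796 genes. Among genes of the panel and of the lists on BET proteins, BET inhibition and trophoblast, the effect at 48 h less that at 24 h was 5.80 for NANOG, 3.73 for ZMYND8, 3.325 for E2F2, 2.92 for CCND2, 1.72 for TFAP2C and 1.32 for BCL2. It was -0.94 for BRD2, -1.77 for HEXIM1, -1.97 for IGFBP3, -2.86 for MYC, -2.99 for ELL2, -3.01 for H2BC21, -3.504 for H2BC12, -3.53 for H2BC5 and -3.87 for GATA2. These are not all the named genes that differed. Pluripotency and epithelial genes given above, such as USP44 and CDH1, are left out here. Time since the inhibitor and Activin A on day 2 differ together in this contrast, so their parts cannot be told apart.

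A signal also appeared in data that no comparison used. The E7_CPI column of replicate 1, read in the gene order of the replicate 2 table, correlated with E7_CPI replicate 2 at a Spearman coefficient of 0.9857 across genes, which are not independent replicates. As deposited it correlated with no library. The lowest correlation with any other library was 0.9539 in that order, against at most 0.0142 in random orders, so values listed in another gene order are a candidate explanation. Preparation together with the other replicate 1 libraries is argued against, since its deviations correlated with those of other groups at -0.055 at most, below the lowest of 0.492 among those groups. A second sequencing of the replicate 2 library stays open. The chi-square per gene between both columns was 3.25, above the value near 1 of counting error alone. It was far below the 96.88 of the closest other pair, which crosses the difference between replicates. The noise of a second run, or of samples prepared together, was not measured. No biological explanation was tested.

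MYC was higher under CPI-203 at 24 h, and its effect was lower at 48 h. With library totals alone MYC still rose by 2.278 (SE 0.51) in E7_CPI vs E7, so the choice between TMM and totals did not matter. The TMM factors ran only from 0.945 to 1.047, so this could not test library scaling as the cause. The single E7_CPI library is argued against by the difference of 1.348 (SE 0.46) in WNT_CPI vs WNT, which holds no E7_CPI library, although that comparison missed the threshold without the replicate block (adjusted p = 0.0572). Exposure to CPI-203, which the design gives, stays open as the biological explanation, since no value apart from the pattern itself was tested for it.

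Streak and endoderm genes differed between replicates at 48 h: definitive endoderm genes were higher in replicate 1 of WNT_ACT in 12 of 14 cases (median difference 1.56) and of WNT_CPI_ACT in 11 of 14 (median 3.93), but in 5 of 14 in E7_ACT (median -0.37) and in 1 of 14 in WNT_E7 (median -0.55). Streak and early mesoderm genes differed less, with 12 of 19 higher in replicate 1 of WNT_ACT (median 0.55) and 15 of 19 in WNT_CPI_ACT (median 1.08), against 8 of 19 in E7_ACT (median -0.03) and 8 of 19 in WNT_E7 (median -0.29). Lower depth of the replicate 2 libraries is argued against, since the total of WNT_CPI_ACT replicate 1 exceeded that of replicate 2 by 0.083 on the log2 scale. A batch shift common to all groups stays open. Over 12 members measured in E7_ACT, the difference in WNT_CPI_ACT less that in E7_ACT had a median of 1.29. The SE of 0.87 is that of the mean over these genes, which are not independent replicates. No biological explanation was tested.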

How the results depend on the processing

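The uses of the reordered E7_CPI column and all values for the difference of the CPI-203 effect between 48 h and 24 h were chosen after the data were seen, as was camera with both the block and an estimated correlation. DESeq2 size factors, library totals alone, no low-count filter and a log2 fold change of at least 1 left every count of called genes, both directions together, within 1.5 times its value. With a log2 fold change of at least 1, the genes called higher alone were 1094 instead of 1941 in WNT_CPI vs WNT and 911 instead of 1467 in E7_CPI vs E7. Except where given otherwise, the cause of a change was not tested. The DESeq2 Wald test called 255 genes in WNT vs E7, 82 in WNT_CPI vs E7_CPI, 16 in the interaction, 962 in WNT_ACT vs E7_ACT, 571 in WNT_ACT vs WNT_E7, 1496 in WNT_CPI_ACT vs WNT_ACT, 349 in E7_ACT vs E7, 7 in WNT_E7 vs WNT and 2721 in the difference between days, and 51 Wnt3a genes also with CPI-203. The replicate block called 414 in WNT vs E7, 7834 in E7_CPI vs E7, 9417 in WNT_CPI vs WNT, 95 in WNT_CPI vs E7_CPI, 7 in the interaction, 2024 in WNT_ACT vs E7_ACT, 1130 in WNT_ACT vs WNT_E7, 3590 in WNT_CPI_ACT vs WNT_ACT, 5695 in WNT_CPI_ACT vs E7_ACT, 741 in E7_ACT vs E7, 7 in WNT_E7 vs WNT and 5923 in the difference between days, with 54 Wnt3a genes kept. It takes out the difference between replicates that all groups share, and the common coefficient of variation fell from 0.29 to 0.122. It does not take out differences that groups do not share, such as those of definitive endoderm genes (median 3.93 in WNT_CPI_ACT and -0.37 in E7_ACT). It ended the call of 0 named genes and added 54. No paired analysis other than this block was run. Fits on the compared groups alone, which have fewer residual degrees of freedom, called 6 in WNT vs E7, 0 in the interaction, WNT_ACT vs E7_ACT, WNT_ACT vs WNT_E7 and WNT_CPI_ACT vs WNT_ACT, 73 in WNT_CPI_ACT vs E7_ACT, 12 in E7_ACT vs E7 and 886 in the difference between days. The stricter filter gave 49 in WNT vs E7.

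The reordered E7_CPI column lies close to replicate 2: their chi-square per gene was 3.25 and their median absolute log2 ratio 0.081, against at least 96.88 and 0.291 in the other pairs of replicates. The other pairs cross the difference between replicates, which the deviations of this column did not follow. These values therefore cannot tell a repeat of the same sample from a separate one. The column may understate the spread and raise the counts. With it added, the counts were 5671 in E7_CPI vs E7, 67 in WNT_CPI vs E7_CPI, 2 in the interaction, 667 in WNT_ACT vs E7_ACT, 153 in WNT_ACT vs WNT_E7, 1024 in WNT_CPI_ACT vs WNT_ACT and 104 in E7_ACT vs E7, with 34 Wnt3a genes kept. In place of replicate 2 it gave 2 in the interaction. Added together with a block that put it with replicate 2, it gave 563 in WNT vs E7, 9801 in E7_CPI vs E7, 9832 in WNT_CPI vs WNT, 308 in WNT_CPI vs E7_CPI, 39 in the interaction, 2502 in WNT_ACT vs E7_ACT, 1553 in WNT_ACT vs WNT_E7, 4195 in WNT_CPI_ACT vs WNT_ACT, 6214 in WNT_CPI_ACT vs E7_ACT, 1071 in E7_ACT vs E7, 8 in WNT_E7 vs WNT and 6486 in the difference between days, with 130 Wnt3a genes kept. Of the 264 list tests, 85 passed camera, 81 with the block (69 of the 85), 16 with an estimated correlation, 1 with both and 50 directional fry.

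Leaving out each library in turn leaves a group with 1 library, which is assumed to vary like the others. The counts ran from 9 to 23 in WNT vs E7, from 1686 to 1736 in E7_CPI vs E7, from 2725 to 2965 in WNT_CPI vs WNT, from 2 to 12 in WNT_CPI vs E7_CPI, from 30 to 315 in WNT_ACT vs E7_ACT, from 0 to 84 in WNT_ACT vs WNT_E7, from 136 to 413 in WNT_CPI_ACT vs WNT_ACT, from 779 to 1100 in WNT_CPI_ACT vs E7_ACT, from 0 to 7 in E7_ACT vs E7 and from 878 to 1383 in the difference between days. They were 0 throughout in the interaction and in WNT_E7 vs WNT. For the genes named by the fixed rule, over all alternatives, 6837 values kept their side of the threshold (a gene not called in either fit may have changed sign), 747 lost the call (172 of them in fits on the compared groups alone), 222 gained it and 0 changed sign while called. No result was computed for the ATAC alternatives and accessibility near changed genes, since the peak list has no values per sample, or for leaving out the lone E7_CPI library. With 36268324 counts in the library of lowest total, depth limits values near 0 counts, where a group without a count allows up to 3 counts.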

Other observations

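The test of the list of genes raised in E7_ACT vs E7 was chosen after the results were seen, and the counts by chromosome were not planned either.

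Of the 626 genes that the RefSeq table places on chromosome 22, 625 had no count in any of the 15 fitted libraries (99.8%), against 8.6% to 23.1% of the genes on any other autosome or X. Of the ATAC peaks, 4841 lay on chromosome 22, with a median width of 424 bp. List members on this chromosome that had no values included ZNRF3, SREBF2, MCM5, ATF4 and XBP1.

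A hypothesis was that cells given CPI-203 on day 1 respond less to Activin A on day 2. The 33 genes called higher in E7_ACT vs E7 served as the list, and it was tested in WNT_CPI_ACT vs WNT_ACT, which shares no library with that comparison. Of the list, 23 genes were lower, 7 of them called, and 3 were called higher (median -0.70). Among all 648 genes called in WNT_CPI_ACT vs WNT_ACT, 469 were lower and 179 higher, so the called members leaned down no more than called genes did. Camera gave p = 0.000569 with the preset correlation and p = 0.258 with an estimated correlation. A weaker response stays open, because camera with an estimated correlation did not call the list. Time and Activin A also differ together in E7_ACT vs E7, and no group received Wnt3a with CPI-203 and then medium alone.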
